A study of Oryza sativa with 4 samples.

How the data were processed

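Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an antibody against histone H4 acetylated at lysine 5 (H4K5ac) on leaves of the rice cultivar Hanyou73 at the grain filling stage. There were 4 libraries, 2 from well-watered and 2 from drought-stressed plants. Per the labels' protocols, leaf tissue was crosslinked with formaldehyde, the chromatin was sheared by sonication, and libraries were built with a commercial Illumina kit. The labels do not say whether the replicates of a condition came from separate plants.

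The data used here are 2 peak lists, 1 per condition. Per the labels, both replicates of a condition point to the same list, so each list stands for its condition as a whole and neither gives a value per replicate. How the replicates entered the lists, whether an input library served as control, the calling threshold and the genome build are not given in the sources used here. Per the submitters' processing notes, the tools included BWA, SAMtools, MACS2 and deepTools, with no versions. Each row of a list holds a chromosome, a start, an end, a peak name and a score. The score is the authors' own value per deposited peak, and its scale is not stated. Scores were therefore used to describe, rank or filter peaks within a list, and to find pairs of like score, by the well-watered score or, in the permutations of pairs, by the geometric mean of both scores. Where the scores of a region are given from both lists, they stand side by side and no change is read from them. Read depth is unknown, since the lists hold no counts. Peak number and peak width both move with depth and with enrichment, so differences between the lists describe these lists. There is no spread between replicates to set against them, and no p-value between conditions is given.

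Coordinates are those of the lists, written 1-based. The lists name chromosomes 1 to 12, Un and Sy. A table of rice genes was compared with the lists to see whether its coordinates could be used. Of the well-watered peak midpoints, 16.0% lay within 500 bp of an end of a protein-coding gene in that table, beside 14.3% to 16.3% after 100 random shifts of the peaks. The table was therefore treated as another build, and no gene was assigned to any peak. The planned gene-level results (positions relative to genes, genes with peaks, 41 gene lists and covered length per gene) are not reported here.

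Peaks were compared by overlap of at least 1 bp (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1; the counts were checked against bedtools 2.31.1). A peak with no overlap is called condition-only. Peaks of the lists that overlapped each other and nothing else were taken as 1-to-1 pairs, and their widths were compared. The overall numbers, widths, covered lengths and overlaps were planned before the data were examined. The comparison of pairs, the score deciles, the divided peaks and the distances were added after the data were seen. The overlap of unrelated lists was estimated from 100 random placements of the drought-stressed peaks within their chromosomes, whose length was taken as the end of the last peak in either list. Shares carry Wilson 95% intervals and medians order-statistic 95% intervals. Both cover counting error only, and treat neighbouring peaks as independent. Peaks named for their score were chosen by the planned rule: the 5 highest-scored peaks of each list and the 10 highest-scored condition-only peaks of each list. That rule also asked for a gene with an informative product, which was dropped because no gene was assigned. The peaks with the largest width changes, the most divided peak and the longest peaks were outside this rule and picked after the data were seen.

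The regional comparisons were likewise added later. Chromosomes were cut into 1 Mb windows, and windows with at least 20 pairs or peaks were compared. Stretches of pairs that widened under drought were found by adding 1 for each wider pair and taking off 2 for each other pair, with no gap over 100 kb. A first definition, the longest unbroken run of wider pairs extended outward, crossed a long peak-free gap on chromosome 12 and was replaced by this one. The highest stretch score was set against 1000 permutations of the direction of change among pairs of like mean width, and to 1000 more among pairs of like mean width and score, with the best stretch searched for again each time. These permutations shuffle peaks within the 2 lists, not samples, and take neighbouring pairs as independent. They describe these lists and are no test of the conditions.

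The procedure was tested on simulated data made from the 28883 well-watered peaks. It recovered 2000 of 2000 dropped peaks, 300 of 300 added peaks, 150 of 150 split peaks, and the 20 pairs of a planted wider stretch. This checks the code only, since the changes were planted without doubtful overlaps. Every planted pair of the stretch widened, on a background with a median change of -40 bp. The simulation therefore does not show how well a stretch is found in the real lists. Alternatives were stricter overlaps, a tolerance of 1 kb, merging of peaks less than 500 bp apart, only peaks above the median score of their list, and the same number of peaks in both lists.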

Results

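H4K5ac, a histone mark associated with transcribed chromatin, was mapped in leaves of well-watered and drought-stressed Hanyou73, a hybrid rice bred for water saving and drought resistance. The data were 1 peak list per condition, each standing for 2 libraries. The well-watered list held 28883 peaks that covered 17.6 Mb. The drought-stressed list held 26147 peaks that covered 14.9 Mb. The sequencing depth behind the lists is unknown, and there are no values per replicate, so each number below describes a list and has no replicate error.

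In both lists the H4K5ac peaks, as called by the submitters, were short and separate. The median width was 611 bp under well-watered conditions (interquartile range 353 to 794 bp) and 570 bp under drought (357 to 730 bp). The shortest peaks measured 139 and 145 bp and the longest 5149 and 5337 bp. Neighbouring peaks lay a median of 6699 bp apart in the well-watered list and 7420 bp apart in the drought-stressed list. Peaks were spread over all 12 chromosomes. Chromosome 3 was the densest, with 97.1 well-watered and 88.7 drought-stressed peaks per Mb. Chromosome 11 was the sparsest, with 57.2 and 50.99 peaks per Mb. The unplaced sequences Un and Sy together held 89 and 84 peaks.

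The density also varied within chromosomes. Over the 367 complete 1 Mb windows, the median was 74 well-watered peaks (interquartile range 52 to 101) and 67 drought-stressed peaks (47 to 90). The fewest well-watered peaks, 19, were found on chromosome 4 both from 10 to 11 Mb and from 17 to 18 Mb. These windows held 17 and 18 drought-stressed peaks, the fewest of that list. The fullest well-watered window, chromosome 4 from 34 to 35 Mb, held 144 peaks. The fullest drought-stressed window, chromosome 3 from 35 to 36 Mb, held 134.

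**Figure D1:**
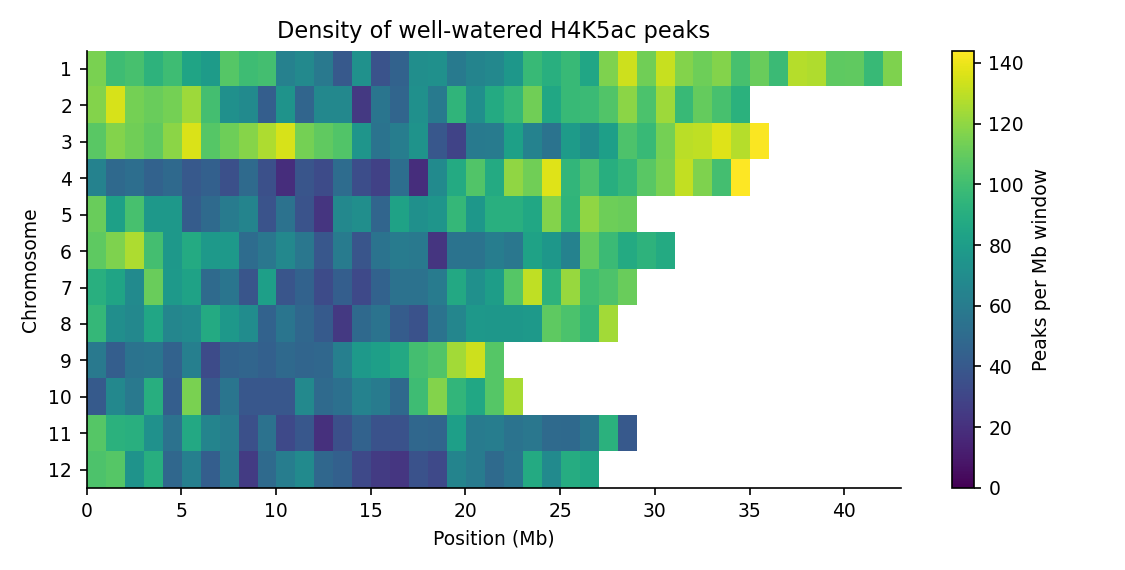
Number of well-watered H4K5ac peaks in each complete 1 Mb window (colour) along the 12 numbered chromosomes (position in Mb, in the coordinates of the lists). Windows range from 19 peaks (chromosome 4, 10 to 11 and 17 to 18 Mb) to 144 peaks (chromosome 4, 34 to 35 Mb).

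The first comparison asked which acetylated regions were found under both water regimes and which under one of them. Most were found under both. Of the drought-stressed peaks, 24868 of 26147 (95.1%, 95% interval 94.8% to 95.4%) overlapped a well-watered peak, against a mean of 9.15% when they were placed at random (range 8.78% to 9.73% over 100 placements). Of the well-watered peaks, 24511 of 28883 (84.9%, 84.4% to 85.3%) overlapped a drought-stressed peak. The lists shared 14.03 Mb, which was 93.9% of the drought-stressed and 79.5% of the well-watered covered length. The well-watered list held 4372 peaks absent from the other list (15.1%) and the drought-stressed list held 1279 (4.89%).

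The regions found under one regime were short and low in score. Well-watered-only peaks had a median width of 221 bp, against 664 bp for shared well-watered peaks, and a median score of 55 against 519. Drought-stressed-only peaks had a median width of 189 bp against 585 bp, and a median score of 45 against 371. In the lowest score decile of the well-watered list, 27.9% of peaks were shared. In the fourth decile 93.9% were shared, and in the ninth all 2888 were. The drought-stressed list went from 67.9% in the lowest decile to 2615 of 2615 peaks in the highest. Among peaks above their list's median score, 24 of 14426 well-watered peaks and 1 of 13067 drought-stressed peaks had no counterpart. With the same number of peaks taken from both lists by score, the counts became 2375 well-watered-only and 1969 drought-stressed-only peaks.

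**Figure D2:**
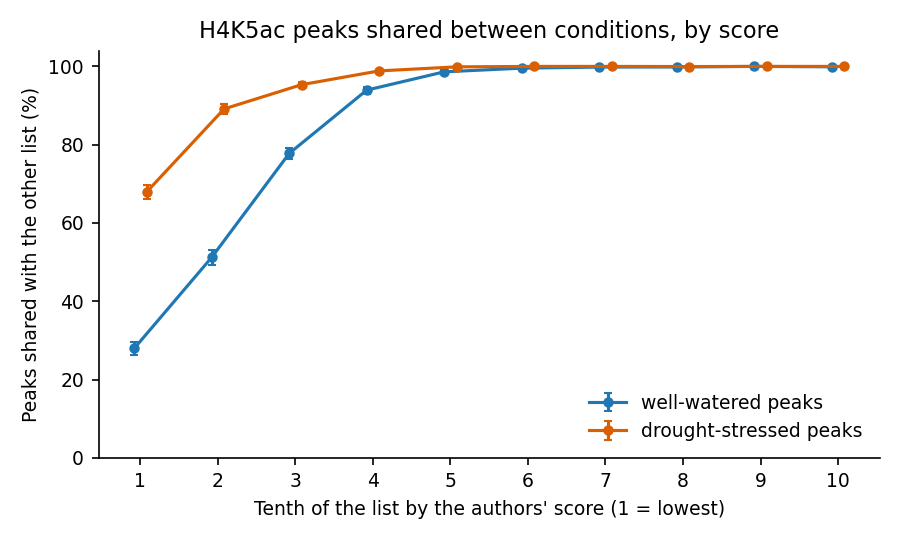
Share of peaks (%) that overlap a peak of the other list, for each score decile of the well-watered (blue) and drought-stressed (orange) list, 1 being the lowest. Bars are Wilson 95% intervals. The shares rise from 27.9% and 67.9% in the lowest decile to 98.6% or more from the fifth decile on.

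The 10 highest-scored peaks found only under well-watered conditions scored 670 to 2109, and 8 of them were at most 160 bp wide. In order of score they lay on chromosome 3 from 20898884 to 20899036 (score 2109), chromosome 12 from 13412004 to 13412144 (1700), chromosome 10 from 5398145 to 5398288 (1567), chromosome 4 from 4110767 to 4111072 (1014) and chromosome 8 from 13308819 to 13308978 (911). They were followed by chromosome 9 from 2851999 to 2852139 (889), chromosome 3 from 13647308 to 13647447 (833), chromosome 4 from 12745608 to 12746043 (708), chromosome 5 from 10152750 to 10152896 (697) and chromosome 9 from 123723 to 123875 (670). The widest was the 436 bp peak on chromosome 4 at 12.7 Mb, whose nearest drought-stressed peak was 74849 bp away. The seventh lay 314 bp from a drought-stressed peak, and the other 9 lay more than 1 kb from one.

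The 10 highest-scored peaks found only under drought scored 205 to 683, and 8 of them were at most 200 bp wide. The highest, on chromosome 6 from 19391 to 19733, was 343 bp wide with a score of 683, and lay 12468 bp from the nearest well-watered peak. The next were on chromosome 1 from 39126998 to 39127166 (score 310), chromosome 6 from 15472901 to 15473058 (265), the unplaced sequence Sy from 396158 to 396341 (245) and chromosome 10 from 3214304 to 3214493 (231). The remaining ones were on chromosome 10 from 10054520 to 10054732 (222), chromosome 5 from 10430404 to 10430554 (222), chromosome 9 from 15432937 to 15433093 (222), chromosome 10 from 1253600 to 1253777 (205) and chromosome 2 from 23296705 to 23296875 (205). Over all condition-only peaks, 1037 of 4372 well-watered-only peaks (23.7%) and 424 of 1279 drought-stressed-only peaks (33.2%) lay within 1 kb of a peak of the other list.

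The highest-scored regions were common to both conditions. The well-watered list was led by chromosome 4 from 4129719 to 4130131 (score 97397), chromosome 11 from 26665748 to 26666563 (85786), chromosome 8 from 7268422 to 7268723 (59418), chromosome 6 from 10176209 to 10176880 (54066) and chromosome 8 from 6525929 to 6526200 (44645). The first 4 of these were also the first 4 of the drought-stressed list, with the leading pair exchanged: chromosome 11 from 26665756 to 26666556 scored 65213 and chromosome 4 from 4129730 to 4130129 scored 59439. The next were chromosome 8 from 7268436 to 7268722 with a score of 45734, and chromosome 6 from 10176353 to 10176848, with a score of 37903. The fifth drought-stressed peak, chromosome 6 from 56036 to 56621 (34281), was ranked 9 in the well-watered list. Of the 1000 highest-scored well-watered peaks, 806 overlapped one of the 1000 highest-scored drought-stressed peaks and 999 overlapped some drought-stressed peak.

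The second comparison asked whether regions acetylated under both regimes had the same extent. Acetylated regions were narrower in the drought-stressed list. Of 23718 1-to-1 pairs, 17816 (75.1%, 74.6% to 75.7%) were narrower under drought, 5743 (24.2%) were wider and 159 were equal. The median difference, drought-stressed minus well-watered, was -53 bp (95% interval -54 to -51 bp, interquartile range -122 to -1 bp), on median widths of 589 and 662 bp. The median shift was 20 bp inward at the left end and 21 bp inward at the right end. Both ends lay inside the well-watered peak in 11240 pairs, and both lay outside it in 2115.

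The median change differed with peak width and was smallest in the narrowest peaks. These lie just above the shortest peaks of the lists (139 and 145 bp), which limits how far they could narrow and still be listed. In the lowest decile of the mean width of a pair, 55.3% of pairs were narrower, with a median of -5 bp, and in the highest 79.6% were, with a median of -73 bp. By well-watered width alone, 55.8% of the pairs in the lowest decile (139 to 281 bp) were wider, with a median of 5 bp, and the median in the highest decile was -109 bp. Sorting by one of the lists makes its narrowest peaks look wider in the other, so the deciles of mean width are the fairer split. By score, the median was below 0 in all 10 deciles. These deciles use the well-watered score alone, so the lowest may look wider under drought for the same reason. It also had the narrowest peaks, with a median well-watered width of 310 bp. In the lowest decile of well-watered score, 59.3% of pairs were narrower, with a median of -27 bp. From the second to the highest decile, 71.1% to 81.5% were narrower, with medians of -49 to -58 bp. Among the 12 numbered chromosomes the share ran from 72.9% on chromosome 10 to 77.04% on chromosome 3. The covered length was lower under drought on each of them, from 0.834 of the well-watered length on chromosome 4 to 0.865 on chromosome 12.

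**Figure D3:**
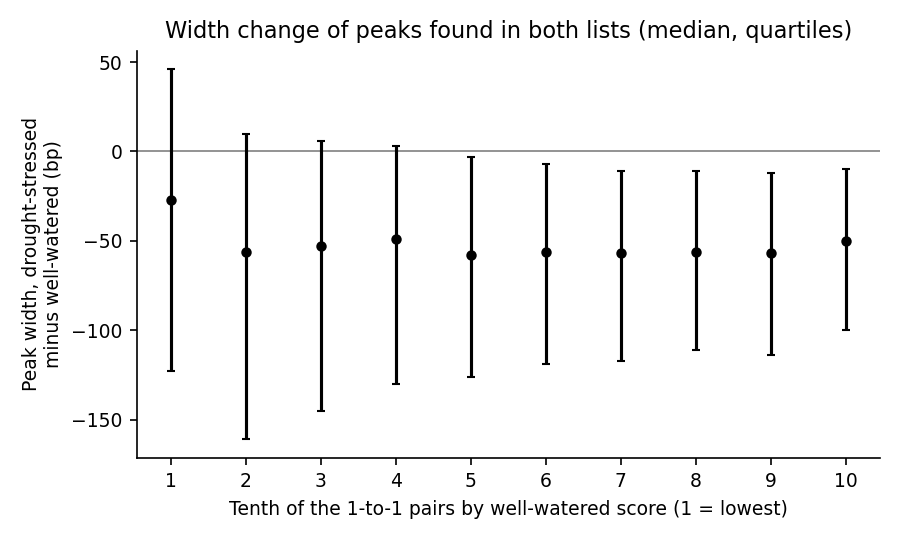
Width of the drought-stressed peak minus that of the well-watered peak (bp) in 1-to-1 pairs, by decile of the well-watered score, 1 being the lowest. Points are medians and bars the interquartile range; all 10 medians lie below 0, between -27 and -58 bp. Sorting by the score of 1 list may make its lowest decile look wider in the other.

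Single regions changed by much more than the median. The largest losses of width were on chromosome 10 from 15874495 to 15876121, a well-watered peak of 1627 bp that met a drought-stressed peak of 169 bp, and on chromosome 2 from 6311935 to 6313652, where 1718 bp met 363 bp. The largest gain was on chromosome 8, where a well-watered peak of 166 bp from 10960034 to 10960199 met a drought-stressed peak of 958 bp. Scores there were low, at 60 and 55. These extremes were picked after their values were seen. Some broad well-watered peaks met several drought-stressed peaks: 498 of them (1.72% of the list, median width 1175 bp) overlapped 2 or more. In the other direction, 156 drought-stressed peaks (0.60% of the list) overlapped 2 or more well-watered peaks. The cause of this difference was not tested. The most divided was the well-watered peak on chromosome 5 from 1547357 to 1549539, 2183 bp wide, over 4 drought-stressed peaks of 158 to 299 bp.

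The narrowing did not hold in a stretch of chromosome 12. From 20464675 to 20668658, 204 kb, 27 of 30 pairs were wider in the drought-stressed list, with a median change of 34.5 bp. The stretch was picked for its wider pairs, so no interval is given for these values. Among the 60 pairs around it, 30 on each side, 17 were wider and the median change was -69.5 bp. But these were broader, with a median well-watered width of 659.5 bp against 208 bp in the stretch. Over all pairs, the lowest decile of mean width (142 to 272.5 bp) had 42.9% wider pairs and a median change of -5 bp. In the well-watered list, the pairs of the stretch had a median score of 410, against 803 for the pairs around it and 534 for all others. In the drought-stressed list, the medians were 586, 552.5 and 390. No scale links the scores of the lists, so each is compared within its own. In 1000 permutations of the direction of change among pairs of like mean width and score, with the best stretch searched for each time, none scored as high as this one (21, against at most 13). The stretch held 31 well-watered and 33 drought-stressed peaks, 15.2 well-watered peaks per 100 kb against 7.72 over all sequences. It was bounded by 332 kb without a well-watered peak on one side and 113 kb on the other. Its peaks were mostly narrow, with a median of 242 bp under drought. It also held the longest peak of both lists, from 20464853 to 20470001 (5149 bp) and from 20464675 to 20470011 (5337 bp). The well-watered peaks of these pairs were narrow for their score, at a median percentile of 2.5 among the 200 pairs of nearest score elsewhere. Signal from a sequence present in many copies cannot be told apart here from a change with drought. The choice of this stretch followed from the data, and leaving it out moved the share of narrower pairs from 75.1% to 75.2%.

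**Figure D4:**
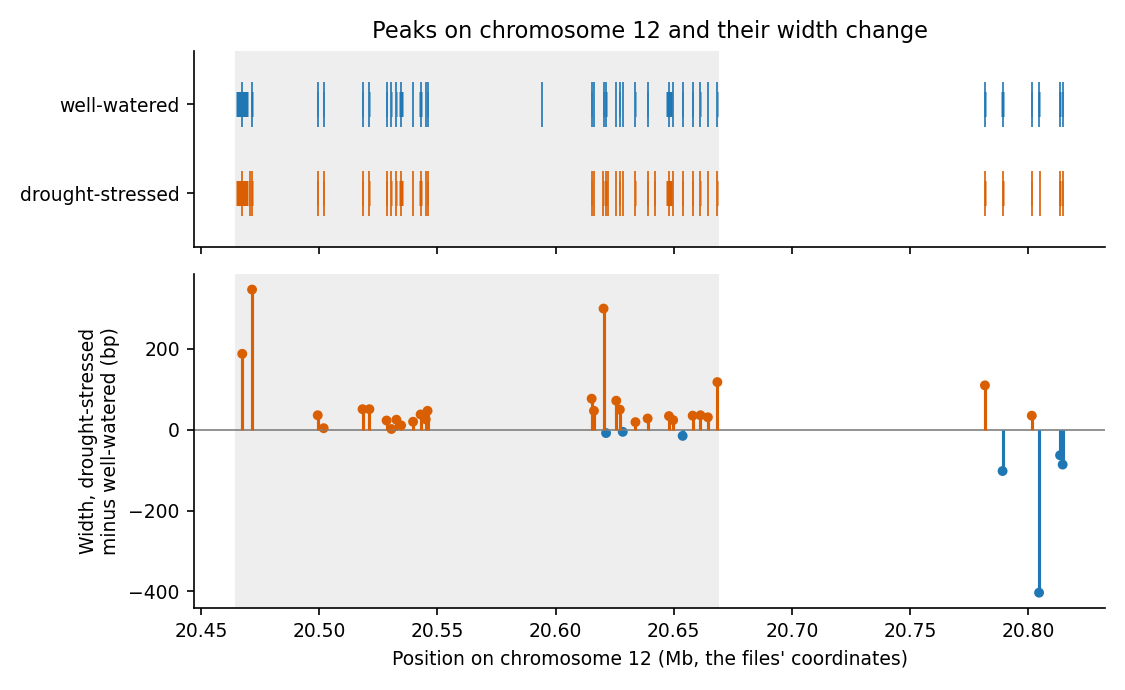
Peaks of both lists on chromosome 12 around the stretch from 20464675 to 20668658 (grey), above, with a bar at peak width and a tick at each peak's midpoint; below, the width change (bp) of each 1-to-1 pair, orange where wider and blue where not wider under drought. Inside the grey area 27 of 30 pairs lie above 0, and the next well-watered peak lies 113 kb after it.

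Regional differences in the loss of peaks were smaller. The share of well-watered-only peaks was highest on chromosome 9 from 7 to 8 Mb, where 17 of 45 well-watered peaks (37.8%) had no drought-stressed counterpart. The highest window in permutations among peaks of like score averaged 31.5% and reached 37.8% or more in 20 of 1000. The spread of this share over the 378 windows was 5.14 percentage points (SD), against 4.97 on average in the permutations, and 115 of 1000 permutations gave as large a spread.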

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

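Tests of peaks above the median score of one list against all peaks of the other, without Un and Sy, without the chromosome 12 stretch and with other window sizes were chosen after the data were seen, as were all alternatives for the 1-to-1 pairs and the ratios with equal numbers. The numbers of condition-only peaks depended on the threshold. With only peaks above the median score in both lists, there were 1721 well-watered-only and 340 drought-stressed-only peaks, and with such peaks of one list against all of the other, 24 and 1. With the same number of peaks in both lists they were 2375 and 1969, and the ratio of peak number is 1 by construction. As only 24 and 1 had no counterpart in the whole other list, most of the 1721 and 340 had one that the cut removed. With equal numbers only the well-watered list was shortened. Drought-stressed-only peaks beyond the 1279 of the full lists therefore had a counterpart that was left out. Other causes were not tested. Reciprocal overlap of 50% gave 6052 and 3316. The share of drought-stressed peaks that were shared, 95.1%, became 93.7% with 50% of the peak covered, 87.3% with reciprocal overlap, 96.7% with a tolerance of 1 kb, 97.4% above the median score, 99.99% above the median score against the whole other list, 92.5% with equal numbers and 95.7% after merging. The share of narrower pairs became 79.3% above the median score and 75.8% with equal numbers; dropping low-scored peaks leaves the widths of the others as they were, so neither is a check of the narrowing. The median width change became -55 bp above the median score and -56 bp after merging. The ratio of covered length stayed below 1 in the 5 alternatives run on it, from 0.820 to 0.880. The lowest window share of narrower pairs was 35.6% in 1 Mb windows, 31.8% in 0.5 Mb windows and 54.8% in 2 Mb windows, each on chromosome 12. Well-watered-only peaks outnumbered drought-stressed-only peaks in each alternative run. This direction was favoured from the start, since the well-watered list was the longer except with equal numbers. With equal numbers, any difference comes from peaks that overlap several peaks of the other list. The direction is therefore little support for more regions being found only under well-watered conditions. The gene-level alternatives were not run, since no gene was assigned to a peak. No paired analysis was possible because each list stands for both replicates of its condition, and for the same reason no replicate could be left out. Unknown depth limits what can be said of the low-scored peaks.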

Other observations

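All tests in this part were chosen after the data were seen, and all concern the 2 peak lists, with 1 list per condition.

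Other stretches of pairs that were wider under drought were shorter than the one on chromosome 12. The next in score, on chromosome 4 from 13927983 to 14124958, held 10 of 10 wider pairs with a median change of 32 bp, and 24 of 1000 permutations gave as high a best score. On chromosome 1 from 33502892 to 33579182, 8 of 8 pairs were wider, with a median change of 15.5 bp, and 298 of 1000 permutations gave as high a score. Next in score were chromosome 6 from 23556468 to 23609846 (7 of 7 wider) and chromosome 10 from 4933182 to 5070285 (8 of 9). As high a best score came up in 700 and 989 of 1000 permutations. In the window of chromosome 10 from 10 to 11 Mb, 14 of 31 pairs were narrower (45.2%), the lowest share after the window of the chromosome 12 stretch. The lowest window share in 1000 permutations among pairs of like mean width ran from 32.1% to 60.6%. Within this window, from 10812015 to 10932906, 8 of 10 pairs were wider, a region outside the highest-scored stretches above. Its highest peaks scored 17500 in the well-watered and 27240 in the drought-stressed list, on scales that are not known to be common. Median well-watered widths in the regions on chromosomes 4, 1 and 10 (from 10812015) were 350, 291.5 and 335.5 bp, at median well-watered scores of 355.5, 1698 and 2918.5. These were narrow for their score: the score deciles concerned had median widths of 641 bp (chromosome 4) and 741 bp (chromosomes 1 and 10). Picking wider pairs favours narrow peaks here too, and no cause was tested.

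On chromosome 12, 27 of 30 pairs of one stretch were wider under drought, a stretch picked for its wider pairs. As high a stretch score came up in 0 of 1000 permutations as chance order among pairs of like mean width, and in 0 of 1000 among pairs of like mean width and score. The second result argues against peaks that are narrow for their score widening everywhere, each on its own, as the whole cause. Both sets of permutations took neighbouring pairs as independent, so they cannot decide where such peaks change together. A candidate explanation is signal from a sequence present in many copies, such as repeats or nuclear copies of organelle DNA: the peaks were narrow for their score, at a median percentile of 2.5 among the 200 pairs of nearest score. This does not decide, since picking wider pairs also favours narrow peaks, the width was seen first, and neither the sequence nor an input library was analysed here. A change of acetylation with drought in this stretch stays open and untested.

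The fewer and narrower drought-stressed peaks may come from less acetylation or from a library-wide difference in depth or enrichment. These cannot be told apart with 1 list per condition and unknown depth: of the drought-stressed peaks above the median score, 0.0077% were absent from the well-watered list, which both explanations allow. Whether one uniform narrowing was the whole cause could not be decided. Without the chromosome 12 stretch, the share of narrower pairs over 1 Mb windows had an SD of 6.91 percentage points. Permutations among pairs of like width and score had a mean SD of 6.15 and a highest of 6.99, with 2 of 1000 reaching the observed value. The excess is small. It is also uncertain, because neighbouring pairs were taken as independent and any likeness between them would raise the SD.

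The 50 highest-scored peaks of the well-watered list had a median width of 488.5 bp, against 743.5 bp for ranks 51 to 1000, and 0 of 10000 draws of 50 peaks from those ranks were as narrow. In the drought-stressed list the widths were 437.5 and 670.5 bp. The well-watered ones had a median of 10 other peaks within 100 kb on each side, against 14 for ranks 51 to 1000, and the drought-stressed ones 11 against 13; the interquartile ranges overlapped in both lists (8 to 14.75 and 9 to 19, 9 to 14.75 and 9 to 18), and these numbers were not tested. No explanation was tested.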
